A study of Mus musculus with 10 samples.

How the data were processed

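The samples were cortices of male C57BL/6 mice aged 2.5 months, perfused before dissection, with 5 control littermates and 5 Atad3 nKO animals. Total RNA was extracted with TRIZOL and treated with DNase, and stranded libraries were made with a total RNA kit that removes ribosomal RNA, with RNA fragmented for 6 minutes, per the labels' protocols. The submitters' processing notes name bcl2fastq, Salmon, DESeq2 and the build mm10, without versions or roles; the annotation release is not given in the sources used here. Salmon assigns reads to transcripts by their sequence and divides reads that fit several transcripts among them, so values of near-identical genes or isoforms depend on that division. Samples were grouped by the genotype label. The labels give no pairing of animals, litter or batch, and the replicate numbers used here only name libraries.

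For each library the authors deposited a gene table and a transcript table. Per the file headers these hold estimated counts (reads assigned per feature, which need not be whole), TPM (scaled by effective length to the same total in every library) and effective lengths. The gene tables list 24972 genes and 42482 RefSeq transcripts are in those for transcripts. Gene values equalled the sums of their transcripts within 2 reads in every library for 99.5% of 24331 genes compared. The tables hold 0 mitochondrially encoded genes, so the list of those genes and their share of counts were not analysed here. The authors also deposited a table of a score for 22 genes, which is centred on each gene's median over the libraries and scaled to a similar spread (SD from 1.08 to 1.32); its scale is not stated, so it served only for directions and correlations.

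Estimated counts were rounded to whole numbers. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14378 genes and 99.9% of the counts of each library. Libraries were scaled by TMM, and CPM below are TMM-scaled. Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a 5% threshold. The SE of a log2 fold change was the estimate divided by the square root of its F statistic, and 95% intervals used the test's degrees of freedom. The median SE was 0.12 on the log2 scale, and 94.9% of genes had a 95% interval within 2-fold. The labels give 1 date, the same for all libraries and of unstated meaning, and running numbers that are lower in every control than in every nKO library. They give no batch or lane, so there is no within-batch value, and if the numbers follow the order of handling, order and genotype cannot be told apart.

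The 34 gene lists (pathways, complexes, cell types, cell states, RNA quality) were fixed before the data were examined, as were the comparisons, tests and the alternatives not described as chosen later. Of these lists 33 had a tested member. They were tested with camera of limma 3.58.1 (preset correlation 0.01), again with an estimated correlation and with fry, each two-sided and adjusted over the lists. Camera compares a list with the other genes. The mean log2 CPM (prior count 2) of each list per library was compared by an exact two-sided permutation test over all regroupings of the 10 libraries, adjusted over 14 cell type and cell state lists and over the 19 others. The smallest p of this design is 0.00794. Single values per library, including TPM on a log2 scale with a pseudocount of 0.1, were tested the same way. Transcript usage was tested with edgeR's diffSpliceDGE (Simes), with no account of the uncertainty of assigning reads to transcripts. Positions came from the RefSeq annotation of GRCm38, the assembly of mm10; 97.7% of the genes had a record by symbol.

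The text names the targeted gene, the 10 genes with the smallest adjusted p and the 5 with the largest change per direction among genes past 5% with a mean CPM of at least 1 (for the change, also without overlap between the groups), and up to 4 members with the smallest p of each list. Genes named outside this rule were chosen after their values were seen. The tests were checked on simulated counts of 14285 genes with known changes set in 200 genes before filtering: edgeR recovered 43 of 99 genes changed 1.5-fold and 75 of 99 changed 2-fold, with 4 false calls. The camera test found a shifted list among genes simulated independently of each other, which does not check its preset correlation. The usage test recovered 13 of 100 genes with 6 false calls among 4370 genes.

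Alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom, other count filters (none, or a CPM of at least 1 in at least 5 libraries), a fit without robust estimation, effective length offsets, sums of transcript estimates, 1 surrogate variable from sva 3.50.0, and each of the 10 libraries left out. Alternatives chosen after seeing the data were 2 pairs of libraries left out, camera on 1 statistic per gene with and without correction for transcript length, summed globin genes, an unadjusted p under 0.05 for genes near Atad3a, and the share of the 10 most abundant genes without Malat1.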

Results

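Total RNA was sequenced from the cortex of male C57BL/6 mice aged 2.5 months, 5 carrying the genotype Atad3 nKO and 5 control littermates. Atad3a, the single mouse gene of the ATAD3 family, encodes an ATPase anchored in the mitochondrial inner membrane. The labels do not spell out nKO, and they name neither the deleted exons nor a driver line. Each library was 1 animal, so the spread given below is the spread between animals. The libraries held 14812639 to 24161361 estimated counts, with 18814419 ± 3123305 (SD, n = 5) in controls and 16774823 ± 1526462 (SD, n = 5) in nKO (exact two-sided permutation test, p = 0.167). Between 16954 and 17492 genes had at least 1 count per library.

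Whether the targeted transcript was lower in every knockout animal was examined first. Atad3a (NCBI gene 108888; mm10 chromosome 4, 155740640 to 155761124) fell from 23.7 ± 1.87 CPM (SD, n = 5) in controls to 11.5 ± 1.97 CPM (SD, n = 5) in nKO, which left 48.5% of the control level. The log2 fold change was -1.04 (SE 0.12, 95% interval -1.30 to -0.78; edgeR adjusted p = 0.00634). The 5 nKO libraries lay between 8.95 and 14.4 CPM and the 5 control libraries between 22.2 and 26.6 CPM, without overlap (exact permutation p = 0.00794, the smallest that this design can give). The files list 1 transcript of the gene, NM_179203, which stood at 30.2 ± 2.09 TPM (SD, n = 5) in controls and 15.6 ± 1.88 TPM (SD, n = 5) in nKO. These values count the reads of all cell types of the cortex together, and a read outside the deleted part of the gene does not report the deletion.

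One further gene fell in the knockout cortex. Fam155a (NCBI gene 270028; mm10 chromosome 8, 9206006 to 9773329), which encodes an auxiliary subunit of the sodium leak channel NALCN, went from 104 ± 7.58 CPM (SD, n = 5) to 62.8 ± 6.03 CPM (SD, n = 5), or 60.1% of control. Its log2 fold change was -0.73 (SE 0.08, 95% interval -0.91 to -0.56; edgeR adjusted p = 0.00634), and its nKO libraries (56.4 to 72.4 CPM) did not overlap the controls (97.3 to 116 CPM). The transcript NM_173446 stood at 60.1 ± 4.93 TPM (SD, n = 5) in controls and 28.7 ± 4.92 TPM (SD, n = 5) in nKO, 47.9% of control (exact permutation p = 0.00794). The second transcript, NM_001347127, stood at 45.4 ± 5.65 and 37.7 ± 6.79 TPM (SD, n = 5 each; exact permutation p = 0.0873). Over the 6 transcripts compared this way, the Benjamini-Hochberg adjusted values were 0.0238 and 0.0873. Only the transcript of Atad3a was planned for this comparison. Those of Fam155a and Cds2 belong to genes called on the same libraries, so their permutation tests are descriptive. A difference between the 2 transcripts was not called: edgeR's test of transcript usage gave Fam155a an adjusted p of 0.99997 by Simes and 0.833 by the gene-level F test.

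**Figure D1:**
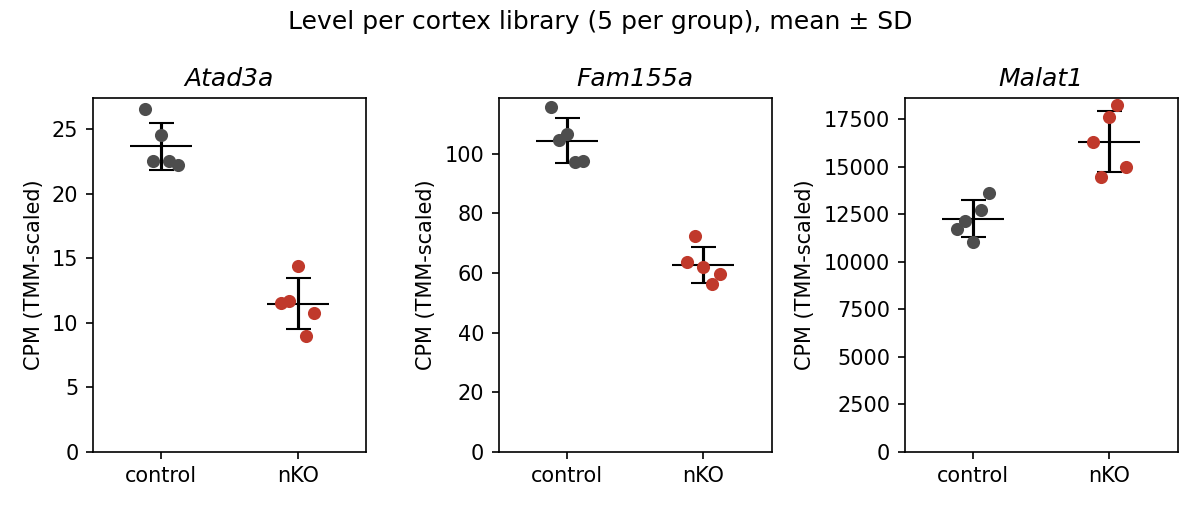
CPM of Atad3a, Fam155a and Malat1 (vertical axes from 0) in each of the 5 control and 5 nKO cortex libraries; points are libraries, horizontal bars the group means and error bars the SD. For each of the 3 genes the groups do not overlap: Atad3a and Fam155a are lower in nKO, at 48.5% and 60.1% of control, and Malat1 lies at 16327 against 12264 CPM.

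Atad3a and Fam155a were the only genes past a 5% false discovery rate among 14378 tested with edgeR's quasi-likelihood test, and no gene passed it in the higher direction. The next smallest adjusted p was 0.718. At an unadjusted p under 0.05 there were 812 genes, 483 higher and 329 lower, where 719 would arise by chance. The 2 groups did not overlap in 198 genes (1.38%), against 0.794% by chance for 5 against 5. Both chance values take genes as independent. Other regroupings of the same libraries gave as few as 98 and as many as 3886 genes at an unadjusted p under 0.05. The excess of 812 over 719 therefore cannot be read as a group effect. DESeq2 called 5 genes, of which 2 were higher and 3 lower: Atad3a, Fam155a, Malat1, Dusp11 and Lcn2, the last 2 named after their values were seen. The precision limits what this comparison could show: the 95% interval of 75.7% of the tested genes lay within 1.5-fold of no change. In simulated data with these depths and dispersions, 43.4% of genes changed 1.5-fold and 75.8% of genes changed 2-fold were recovered. That simulation changed 200 genes and drew all genes independently of each other. With fewer changed genes the adjustment is stricter, so these shares can overstate the recovery in the real data.

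The nuclear genes of the respiratory chain, which carries electrons to oxygen and drives ATP synthesis, lay slightly lower in nKO. Of 36 subunits of complex I, 34 were lower and 2 higher, with a median log2 fold change of -0.11 (camera with a preset correlation, adjusted p = 9.1e-07). Of 39 subunits of complexes II to V, 36 were lower and 3 higher, with a median of -0.09 (adjusted p = 1.4e-06). The estimated correlations between members were 0.13 and 0.18, well above the preset 0.01, so the p-values with the preset can be too small. With the estimated correlations both lists had camera adjusted p = 0.300. No member passed 5%, either over all genes or adjusted over the list alone. Atp5b, the catalytic beta subunit of ATP synthase, stood at 1129 ± 40.2 CPM (SD, n = 5) in controls and 1002 ± 41.7 CPM (SD, n = 5) in nKO, a log2 fold change of -0.17 (SE 0.06). Cyc1, cytochrome c1 of complex III, had a log2 fold change of -0.31 (SE 0.11), and the complex I subunit Ndufv1 had -0.28 (SE 0.12); without control 1 and nKO 4, which was chosen after seeing the data, these came to -0.20 and -0.13. The mean log2 CPM of the list per library was 0.14 lower for complex I (5.71 ± 0.11 against 5.57 ± 0.10; SD, n = 5 each; exact permutation p = 0.0476) and 0.12 lower for complexes II to V (exact permutation p = 0.0317). After adjustment over 19 lists both came to 0.151. A difference in a single list could not pass this adjustment, so the result does not show that either list was unchanged.

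Mitochondrial ribosome proteins, which translate the genes of the mitochondrial genome, and genes that shape the inner membrane moved the same way. Of 79 ribosome proteins 61 were lower and 18 higher (median log2 fold change -0.08, camera adjusted p = 0.00115), and of 23 inner membrane genes 18 were lower and 5 higher (median -0.09, camera adjusted p = 0.00814). With the estimated correlations of 0.04 and 0.07 both had camera adjusted p = 0.300. For the inner membrane genes the call was also lost without control 3 (camera adjusted p = 0.0516). No member of either list passed 5% over all genes or adjusted over the list alone. Afg3l2, a protease subunit of the inner membrane, had a log2 fold change of -0.18 (SE 0.07), and Samm50, a partner of the cristae-organizing complex in the outer membrane, had -0.17 (SE 0.07). Mrps23 stood at -0.23 (SE 0.09). Without controls 1 and 3 together, which was chosen after seeing the data, Afg3l2 came to -0.12 and Mrps23 to -0.14. Mrpl12 stood at 23.5 ± 11.0 CPM (SD, n = 5) in controls and 12.2 ± 1.39 CPM (SD, n = 5) in nKO; its log2 fold change of -0.95 (SE 0.27) became -0.39 without the same controls.

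**Figure D2:**
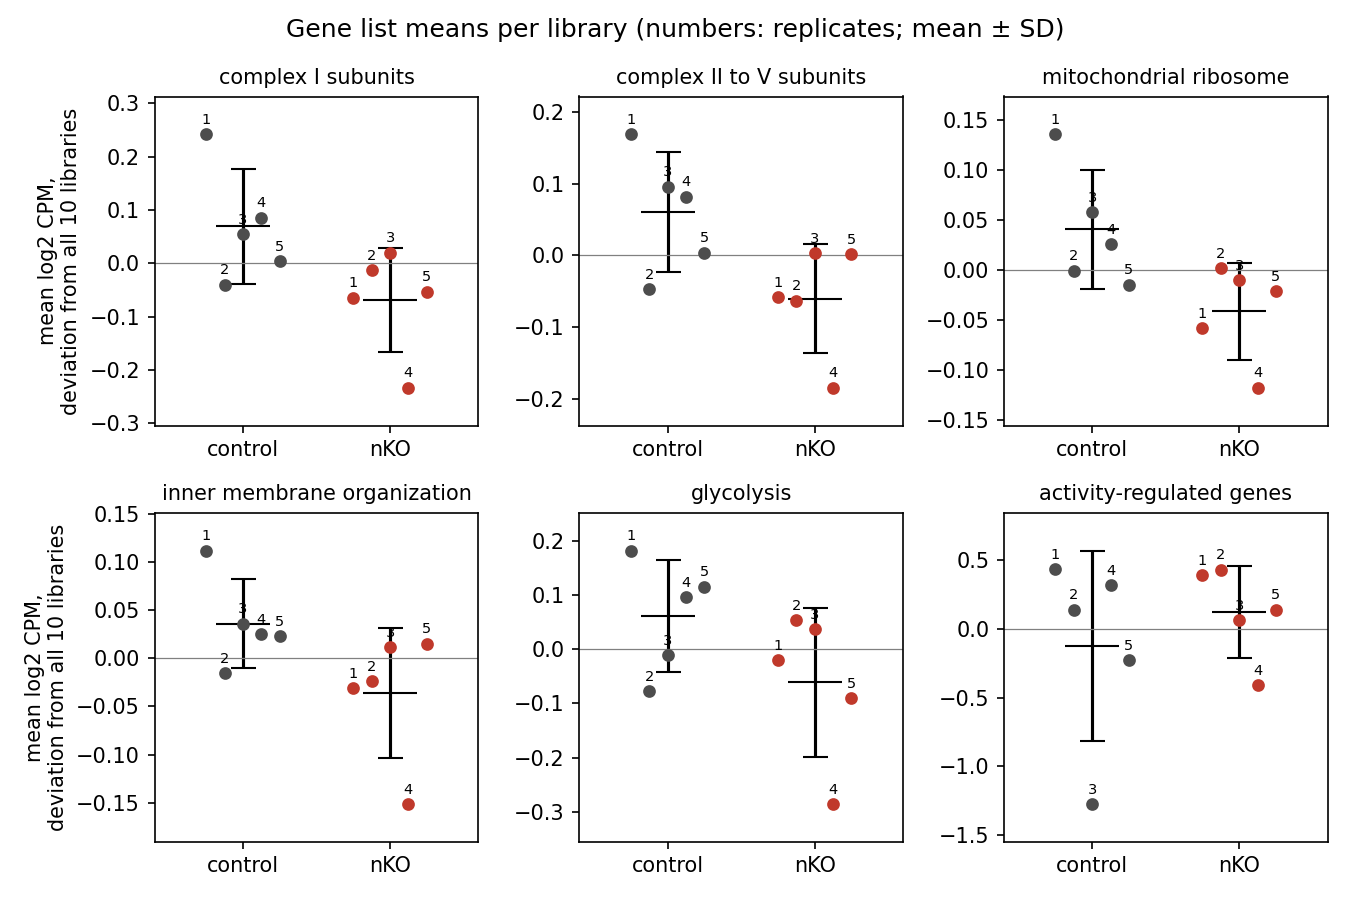
Mean log2 CPM of 6 gene lists in each library, drawn as the deviation from the mean of all 10 libraries (vertical axes differ between panels and do not start at a common value); points are libraries, the number beside each point is its replicate, and bars give the group mean ± SD. Control 1 is the highest and nKO 4 the lowest library in the 4 mitochondrial panels and for glycolysis, and control 3 lies at -1.27 for activity-regulated genes.

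Transcript length and 2 libraries moved with these groups. Across the tested genes, which are not independent replicates, the log2 fold change rose with transcript length (Spearman's rho 0.30), from a median of -0.07 in the shortest quartile to 0.05 in the longest. The median transcript length was 719 bases for complex I, 716 bases for complexes II to V and 1065 bases for the mitochondrial ribosome, against 2994 bases over all tested genes. On the first principal component, which held 33.6% of the variance, control 1 (-46.8) and nKO 4 (29.8) were the ends. Without these 2 libraries, an alternative chosen after seeing the data, the same 2 genes were called, complexes I, II to V and the mitochondrial ribosome stayed past 5% (camera adjusted p = 0.00499, 6.1e-04 and 0.0266), and the inner membrane genes did not (0.0663). After correction of the gene statistics for length, also chosen after seeing the data, the mitochondrial ribosome (adjusted p = 0.302, median 0.00033), the inner membrane genes (0.0903, median -0.07) and the blood cell genes (0.105, median -0.70) no longer passed. The same form of camera without the correction gave 0.000853, 0.00552 and 0.00438. Complex I, complexes II to V and glycolysis still passed (camera adjusted p = 0.0112, 0.0286 and 0.0026). Their medians after the correction were -0.01, 0.01 and -0.09.

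Of 21 genes of glucose uptake and glycolysis, 18 were lower and 3 higher. Their median log2 fold change was -0.09 (camera adjusted p = 2.5e-04, and 0.420 with the estimated correlation of 0.29). No member passed 5% over all genes or adjusted over the list alone. Lactate dehydrogenase B (Ldhb) stood at 426 ± 29.2 CPM (SD, n = 5) in controls and 366 ± 26.6 CPM (SD, n = 5) in nKO, a log2 fold change of -0.22 (SE 0.07). The enolase gene Eno1 had -0.35 (SE 0.12) and pyruvate kinase Pkm -0.27 (SE 0.11). Control 1 and nKO 4 were again the highest and lowest libraries, and without both the list had camera adjusted p = 0.0688, with Eno1 at -0.20 and Pkm at -0.11.

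Activity-regulated genes, which neuronal firing induces, were the only list past 5% in the higher direction. Of 22 members 19 were higher and 3 lower. Their median log2 fold change was 0.20 (camera adjusted p = 0.0131, and 0.494 with the estimated correlation of 0.43). No member reached an unadjusted p under 0.05: Egr1 had a log2 fold change of 0.40 (SE 0.26) and Fosl2 of 0.40 (SE 0.23). Without control 3 these came to 0.21 and 0.23, and Egr1 was at 0.66 without control 4. Control 3 lay 1.27 below the mean of all libraries on this list, and without it the list had camera adjusted p = 0.762. The call was also lost without control 5 (adjusted p = 0.110), nKO 1 (0.119) or nKO 2 (0.118), and with the form of camera that takes 1 statistic per gene (0.110).

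Blood cell genes were low in these perfused cortices, with 6 of 15 listed genes passing the count filter. The listed beta-globin gene Hbb-bt, with reads in 4 nKO and 0 control libraries, did not pass it. The list's values below therefore leave out a member that went the other way. Of the 6 tested, 5 were lower and 1 higher in nKO. Their median log2 fold change was -0.86 (camera adjusted p = 5.6e-04, and 0.300 with the estimated correlation of 0.17). The neutrophil gene S100a9 stood at 2.16 ± 1.62 CPM (SD, n = 5) in controls and 0.990 ± 0.366 CPM (SD, n = 5) in nKO, where its log2 fold change of -1.17 became -0.61 without control 3, and the beta-globin gene Hbb-b2 at 3.64 ± 1.93 and 0.232 ± 0.518 CPM (SD, n = 5 each). Hbb-b2 was the 1 member past 5% adjusted over the list alone, and 0 passed over all genes; its reads are shared with near-identical globin genes, so its own level is uncertain. The sum of the adult beta-globin genes was 23.4 ± 13.4 CPM (SD, n = 5) in controls and 14.6 ± 8.15 CPM (SD, n = 5) in nKO, a difference that edgeR did not call (adjusted p = 0.837). The list's call was lost without control 2, 3, 4 or 5 or nKO 1 (camera adjusted p from 0.130 to 0.328). Leaving out 1 library also changed which genes passed the filter, and whether the list's tested members differed there was not examined.

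The other mitochondrial and metabolic lists did not pass 5% by camera. Among 23 genes of mitochondrial DNA maintenance 17 were lower (median log2 fold change -0.06, adjusted p = 0.0675), and the mitochondrial topoisomerase Top1mt stood at -0.33 (SE 0.12). Among 16 mitochondrial chaperones and proteases 10 were lower (median -0.01, adjusted p = 0.174), with the HSP90 homologue Trap1 at -0.21 (SE 0.07), or -0.14 without controls 1 and 3. Their mean log2 CPM per library was 5.45 ± 0.03 in controls and 5.38 ± 0.03 in nKO (SD, n = 5 each), without overlap. The exact permutation p was 0.00794, the smallest of this design, and came to 0.151 after an adjustment that a single list could not pass. Mitochondrial phospholipid genes (11 of 17 lower, adjusted p = 0.327) and genes of mitochondrial dynamics and mitophagy (13 of 20 lower, adjusted p = 0.310) did not pass. Nor did cholesterol synthesis, with 19 of 25 genes lower (median -0.06, adjusted p = 0.202); its member Mvk, mevalonate kinase, stood at -0.46 (SE 0.24), at -0.21 without control 1 and at -0.096 without control 1 and nKO 4. Serine and one-carbon metabolism had 11 of 20 lower (adjusted p = 0.202) and the antioxidant response 12 of 19 lower (adjusted p = 0.202).

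Stress response lists did not move past the test either. Targets of the integrated stress response, the ATF4 programme that mitochondrial dysfunction can induce, had 21 of 31 tested members lower and 10 higher, with a median log2 fold change of -0.05 (camera adjusted p = 0.202). The serine synthesis enzymes Phgdh and Psph, which belong to that programme, stood at -0.29 (SE 0.14) and -0.30 (SE 0.14), and the seryl-tRNA synthetase Sars at -0.18 (SE 0.07); without control 1 and nKO 4, Phgdh came to -0.11 and Sars to -0.11. The endoplasmic reticulum stress list had 10 of 16 members higher (median 0.02, adjusted p = 0.732), p53 targets 9 of 14 lower (median -0.03, adjusted p = 0.580) and interferon-stimulated genes 14 of 21 higher (median 0.06, adjusted p = 0.427). No member of these 4 lists passed 5% over all genes or adjusted over the list alone. The interval of the median tested gene, at an SE of 0.12, leaves changes of this size open.

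**Figure D3:**
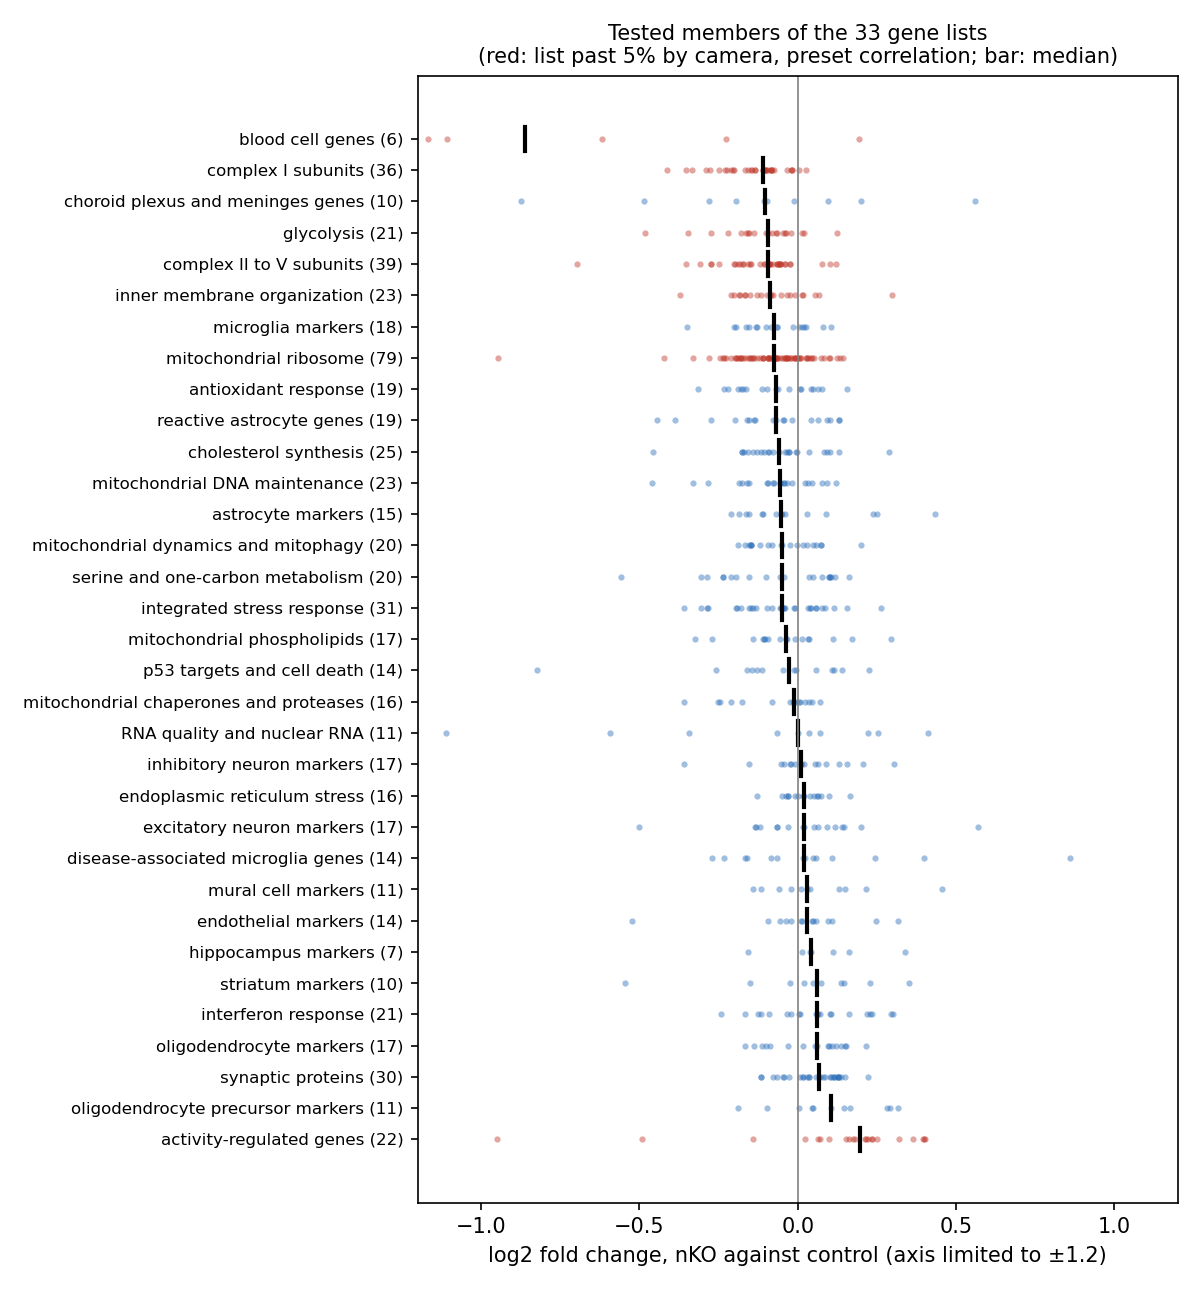
Log2 fold change (nKO against control, horizontal axis, limited to ±1.2, so that 2 members are not drawn) of each tested member of the 33 gene lists, with the number of tested members in brackets; each point is a gene, black bars are medians, and red lists pass 5% by camera with a preset correlation. The 6 red lists with medians below 0 include complex I (median -0.11), and activity-regulated genes (median 0.20) are the red list above 0; none of the 7 passes with an estimated correlation.

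Markers of the cell types of the cortex gave no list past 5% by camera. Excitatory neuron markers were higher in 10 of 17 (median log2 fold change 0.02, adjusted p = 0.311) and inhibitory neuron markers in 10 of 17 (median 0.01, adjusted p = 0.327); synaptic proteins were higher in 23 of 30 (median 0.07, adjusted p = 0.0557). Tbr1, a transcription factor of deep-layer excitatory neurons, stood at 34.5 ± 6.55 CPM (SD, n = 5) in controls and 51.1 ± 8.71 CPM (SD, n = 5) in nKO, a log2 fold change of 0.57 (SE 0.14). It passed 5% adjusted over the list alone (edgeR adjusted p = 0.0269) and not over all genes (0.820). Oligodendrocyte precursor markers were higher in 9 of 11 (median 0.10, adjusted p = 0.0534), with Bcas1 at 0.28 (SE 0.10), and mature oligodendrocyte markers in 11 of 17 (median 0.06, adjusted p = 0.202).

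Astrocyte markers split: 10 of 15 were lower (median log2 fold change -0.05, camera adjusted p = 0.427), with the gap junction gene Gja1 at -0.18 (SE 0.06) and the glutamate transporter Slc1a2 at 0.24 (SE 0.07). Reactive astrocyte genes were lower in 13 of 19 (median -0.07, adjusted p = 0.338). Microglia markers were lower in 12 of 18 (median -0.08, adjusted p = 0.202), with the receptor Trem2 at -0.35 (SE 0.15), or -0.21 without control 1 and nKO 4, and disease-associated microglia genes were higher in 8 of 14 (median 0.02, adjusted p = 0.716). Endothelial markers were higher in 9 of 14 (median 0.03, adjusted p = 0.427), with the vascular receptor Flt1 at 0.32 (SE 0.10), and mural cell markers in 7 of 11 (median 0.03, adjusted p = 0.427). Choroid plexus and meningeal genes (7 of 10 lower, adjusted p = 0.858), striatal markers (7 of 10 higher, adjusted p = 0.496) and hippocampal markers (6 of 7 higher, adjusted p = 0.202) watched for neighbouring tissue. Prox1, a gene of the dentate gyrus and of some interneurons, stood at 0.34 (SE 0.10) and passed 5% adjusted over the list alone (edgeR adjusted p = 0.0255), and 0 members of the hippocampal list passed over all genes. Of the 14 cell type and cell state lists, none had a group difference in mean log2 CPM past 5% after adjustment (exact permutation tests, smallest adjusted p = 0.444). A difference in a single list could not pass this adjustment, so the result does not show that any of them was unchanged.

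A nuclear RNA differed between the groups. Malat1, a long non-coding RNA retained in the nucleus, stood at 12264 ± 985 CPM (SD, n = 5) in controls and 16327 ± 1619 CPM (SD, n = 5) in nKO without overlap (exact permutation p = 0.00794, 0.0198 after adjustment over 5 library measures). Its log2 fold change of 0.41 (SE 0.08) did not pass edgeR's test over all genes (adjusted p = 0.718), passed DESeq2's (adjusted p = 0.0387) and was adjusted over the list alone to 0.00186. The 10 most abundant genes took 4.03 ± 0.165% of the counts (SD, n = 5) in controls and 4.47 ± 0.139% (SD, n = 5) in nKO (exact permutation p = 0.00794, adjusted 0.0198). The Malat1 level and the TMM scaling factor were not among the planned library measures. The adjustment over 5 was therefore not fixed beforehand, and the permutation test of Malat1 is descriptive. Malat1 is among the 10 most abundant genes, and the other 9, a measure chosen after seeing the data, took 2.79 ± 0.116% and 2.85 ± 0.0687% (SD, n = 5 each, exact permutation p = 0.460). The nuclear Kcnq1ot1 stood at 0.22 (SE 0.08), or 0.14 without control 1 and nKO 4. The list of nuclear and RNA quality genes as a whole had 5 of 11 members higher and camera adjusted p = 0.371; its test pointed up, while its mean log2 fold change was -0.31 and its median -0.00049, and Malat1 was its 1 member past 5% adjusted over the list alone.

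The deposit includes a table of scores for 22 genes, centred by the authors on each gene's median, which was set beside the counts. By score 14 genes were higher and 8 lower in nKO, and all 22 had the same sign in the count comparison. Each of the 22 had an unadjusted p under 0.05 there (largest 0.0290), and 2 passed 5%, Atad3a and Fam155a. Of the 22 genes with the smallest p, 13 were in the table. The table also holds Malat1, Tbr1, Gja1 and Mrpl12, described above. Since these genes appear to have been chosen on the same libraries, their shared direction is not independent evidence.

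Transcript usage was compared in 4732 genes with at least 2 tested transcripts, to look for a shift between isoforms without a change of the gene. One gene passed 5% in edgeR's test: Cds2, an enzyme that makes CDP-diacylglycerol, a precursor of cardiolipin (adjusted p = 0.0042). Its transcript NM_001291039 stood at 5.36 ± 4.63 TPM (SD, n = 5) in controls and 41.9 ± 32.8 TPM (SD, n = 5) in nKO (exact permutation p = 0.0159), and the main transcript NM_138651 at 258 ± 15.5 and 212 ± 31.7 TPM (SD, n = 5 each; exact permutation p = 0.0159); both came to 0.0238 after adjustment over 6 transcripts. The comparison of these transcripts was not planned and follows the call of Cds2 on the same libraries, so it is not independent evidence. The Cds2 gene as a whole stood at a log2 fold change of -0.10 (SE 0.05). In simulated data this test recovered 13 of 100 changed genes and made 6 false calls, and without single libraries it called up to 9 genes, so the count of 1 is not firm.

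Genes near the targeted locus were examined because a modified allele can carry flanking sequence of another strain. Within 10 Mb of Atad3a, 0 of 123 tested genes were called by edgeR (Fisher's exact test against the rest, p = 1, with 1 called gene elsewhere), and 7 of them (5.69%) had an unadjusted p under 0.05, against 5.65% of the 14001 genes elsewhere.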

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

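The tests of explanations in this part, and the patterns they address, were chosen after the results were seen. Within groups of 5, a library whose gap to its neighbour took up more than 0.71 of the group's range (Dixon's criterion) was listed, over 74 reported values. Of 148 groups of values 16 were listed, where chance gives about 1 in 20 groups, or 7.4. Library nKO 4 accounted for 6 of them, control 1 and nKO 5 for 3 each.

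In nKO 4 the mean of the inner membrane genes was the lowest of its group (ratio 0.721), as were those of mitochondrial phospholipid genes (0.720), inhibitory neuron markers (0.779) and hippocampal markers (0.842). In the same library Cyc1 stood at 61.4 CPM, where the other nKO libraries lay between 81.2 and 85.7 (ratio 0.816), and Pkm at 648 CPM, where they lay between 882 and 950 (0.773). Control 1 was the highest of its group for synaptic proteins (0.747), hippocampal markers (0.735) and nuclear and RNA quality genes (0.719). In nKO 5 reactive astrocyte genes were the highest (0.741), oligodendrocyte precursor markers the lowest (0.716), and Top1mt stood at 6.43 CPM against 8.16 to 8.68 (0.771). In nKO 3 the blood cell genes were the lowest of the group (0.758). Control 3 had 17492 detected genes, against 17166 to 17235 in the other controls (0.788), and was the deepest library at 24161361 estimated counts. Control 4 held the Cds2 transcript NM_001291039 at 13.4 TPM, against 2.12 to 5.01 in the other controls (0.744).

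Hbb-b2 had reads in nKO 1 alone among the nKO libraries (1.16 CPM, ratio 1). In the whole set it had 19.2 to 131 estimated reads in all 5 controls and nKO 1, while its near-identical neighbour Hbb-bt had 18.8 to 59.0 in the other 4 nKO libraries and none elsewhere, so each of the 10 libraries held exactly 1 of the pair (Fisher's exact test by group, p = 0.0476). A different amount of blood predicts that both genes follow the beta-globin sum, but 0 of 5 controls had a Hbb-bt read although their beta-globin sum was not below that of nKO. An arbitrary split of reads between near-identical genes stays open, since all reads of the alpha-globin pair also went to 1 of its genes in 8 of 10 libraries; the files hold no measure of that uncertainty. A different beta-globin haplotype in 4 nKO animals is a candidate explanation that these values do not test.

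The fall of Fam155a may come from its own locus. A regional effect is argued against by the 14 tested genes within 3 Mb, whose median log2 fold change was 0.027 (SD 0.16), far above the upper 95% bound of Fam155a. Complete loss of 1 copy's output in all cells predicts a log2 fold change of -1, below the lower bound of -0.91 for the gene as a whole. By transcript, the log2 ratio of mean TPM was -1.06 for NM_173446 and -0.27 for NM_001347127, a difference that the usage test did not call. A loss limited to 1 transcript was not tested. A partly disrupted copy, such as by an inserted driver transgene, is compatible with a bound of -0.56, but cannot be told apart from a response to the loss of Atad3a, because the labels name no driver and the same 5 animals would carry both. As for chance, 1 of 100 splits of the 10 libraries, the real one, gave at least 2 genes past 5%, and the highest of the others gave 1, but this count includes the deleted gene, which favours the real split by design. Besides Atad3a, 4 of 100 splits, the real one included, gave at least 1 gene, and the highest of the others also gave 1. These were 100 of the 126 possible splits, and the count takes any gene past 5%. It therefore cannot exclude chance for Fam155a.

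For the lower oxidative phosphorylation, glycolysis and related lists, chance cannot be excluded: 13 of 100 splits gave at least as many lists past 5% as the real 7, and the highest of the others gave 12. The count took any list in either direction. How often these lists themselves passed in the splits was not counted. A transcript length trend is argued against for glycolysis, which kept a median log2 fold change of -0.09 after correction (adjusted p = 0.0026), while the mitochondrial ribosome went from -0.08 to 0.00033 (SD over members 0.14) and lost its call (adjusted p = 0.302). For complexes I to V it cannot be told apart: the test stayed past 5% (highest adjusted p = 0.0286), but the medians went from -0.11 and -0.09 to -0.01 and 0.01 (SD over members 0.12 and 0.15), the last with the opposite sign to its test. Without control 1 and nKO 4, complexes I to V and the mitochondrial ribosome stayed past 5% by camera with the preset correlation (highest adjusted p = 0.0266). Glycolysis did not (0.0688). With an estimated correlation none of these lists passed even with all libraries. The test therefore cannot decide whether these 2 libraries were the whole cause. A lower expression in response to the loss of Atad3a is a biological hypothesis that stays open.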

How the results depend on the processing

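Atad3a and Fam155a kept their direction and stayed past 5% in all 22 alternatives, 2 of them chosen after seeing the data, with log2 fold changes from -1.15 to -0.93 and from -0.80 to -0.67. The count of called genes was 5 with DESeq2's Wald test, 3 without nKO 1 and 2 in the other alternatives. The 31 genes besides Atad3a that the rule names kept their direction and side in 681 of 682 values, the exception being Malat1 with DESeq2. Of 7 genes named after their values were seen, not counting Hbb-bt, 6 were tested by edgeR and did so in 131 of 132 values, the exception being Dusp11 with DESeq2. Lcn2 did not pass edgeR's filter. The group difference in the share of the 10 most abundant genes, 0.448 percentage points, was 0.056 without Malat1. The count of lists past 5%, 7, became 0 with an estimated correlation, 0 by fry, and 11 with 1 surrogate variable, all 7 among them. Without control 1 and nKO 4 it was also 11, but these held 5 of the 7, with inner membrane genes and glycolysis lost. The form of camera used for the length correction, which takes 1 statistic per gene, gave 6 before the correction, without the activity-regulated genes (adjusted p = 0.110), and 3 after it. Leaving out 1 library gave 5 to 13, the highest without control 1, where all 7 were among the 13. Lists gained in such settings are among those described above as not passing, so that result also depends on the setting. No mean of a cell type list passed in any of 13 alternatives, but a difference in a single list could not have passed the adjustment in them. The count of genes with changed transcript usage, 1, became 2 to 9 when 1 library was left out, and 2 or more in each of those 10 settings; Cds2 passed in all 12 alternatives (adjusted p up to 0.0423). Of 100 splits of the libraries 83 gave at least 1 such gene and the highest of the others gave 8, so chance cannot be excluded for that count. Near Atad3a, the Fisher test on called genes had only 1 called gene to place and says nothing about stability; on genes with an unadjusted p under 0.05 it gave p = 0.799, 1 and 0.762 within 5, 10 and 20 Mb, chosen after seeing the data. Where fewer libraries or another statistic did not itself account for a change, the cause was not tested. At a common biological coefficient of variation of 0.16, 43.4% of genes changed 1.5-fold were recovered in simulation. The simulation changed 200 genes, so this share can overstate recovery where fewer genes change. Smaller changes were not simulated.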

Other observations

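The authors' 22 scored genes include several whose groups did not overlap in counts and that the report has not described, named here after their values were seen. Wasf2, an actin regulator, stood at 6.28 ± 1.87 CPM in controls and 10.3 ± 1.44 CPM in nKO (SD, n = 5 each), a log2 fold change of 0.72 (SE 0.20), and the vesicular polyamine transporter Slc18b1 at 6.69 ± 1.04 and 10.3 ± 1.04 CPM, 0.62 (SE 0.13). The potassium channel Kcnk2 stood at 23.5 ± 3.07 and 33.9 ± 4.37 CPM, 0.53 (SE 0.12), and Dusp11, an RNA phosphatase, at 45.1 ± 4.74 and 60.5 ± 3.02 CPM, 0.42 (SE 0.08). None of these passed 5% by edgeR, whose adjusted p was 0.718 for Dusp11 and 0.820 for the other 3; DESeq2 gave Dusp11 adjusted p = 0.0329. Lower in nKO by both score and count were Klhdc3 (log2 fold change -0.57, SE 0.15) and the tubulin chaperone Tbcb (-0.31, SE 0.11), neither past 5%. The groups overlapped for Klhdc3 and did not for Tbcb. Without control 1 and nKO 4 the log2 fold changes of Klhdc3 and Tbcb came to -0.34 and -0.16.

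Lcn2, the lipocalin of reactive astrocytes that DESeq2 called, rested on few reads: 51.3 and 59.4 estimated counts in controls 1 and 2, 5.03 to 10.1 in the other controls, and 0 to 3.02 in nKO. A count of 0 allows up to 0.203 CPM in the shallowest library, nKO 5, from counting error alone.

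The trend with transcript length described in the report was also looked at in each library; this restates that trend on the same data and is not independent evidence of it. The Spearman correlation across genes of a library's deviation with transcript length was -0.11 ± 0.09 in controls and 0.10 ± 0.10 in nKO (SD, n = 5 each), and the groups overlapped: control 2 stood at 0.043, above nKO 2, 3 and 5 (0.0076, 0.030 and 0.029).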
